A study of Mus musculus with 35 samples.

How the data were processed

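Gene expression was measured in the livers of 35 adult male C57Bl/6 mice, a common inbred laboratory strain. Per the labels' protocols, each mouse breathed air or styrene vapour once, for 6 hours, in a cage of its own, and was killed the next morning. Styrene is the monomer of polystyrene plastics and is oxidised in the liver and lung to styrene oxide. The 7 groups were air alone and styrene at 1, 5, 10, 20, 40 and 120 ppm, with 5 mice in each and 1 array per mouse. RNA was extracted with Trizol and silica columns and labelled with a biotin kit for Affymetrix 3' IVT arrays, per the labels. Such arrays read each transcript near its 3' end with sets of short probes, called probe sets.

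The deposited table held 1 value per probe set and array on a log2 scale. The submitters' processing notes name RMA and Partek, with no version, role or order. The base of the logarithm is not stated in the sources used here. It was taken as 2 from the range of the deposited values, 1.74 to 14.23, and each fold change rests on that reading. No background correction or normalization was added. No scanner images or probe-level values were used here, so the share of probe sets above background was not determined, and array number limits the precision. Probe sets of low value are bounded by the array's noise, and their changes can be understated.

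The table held 45141 probe sets. The 104 control probe sets were left out of the tests, which left 45037. A platform annotation table paired 28898 probe sets with 1 gene symbol, for 17097 genes. Another 551 probe sets had several symbols and 15588 have no symbol here, and none of these was given a gene name. Symbols were looked up through gene identifiers in a gene table of the GRCm38.p6 mouse assembly, which changed 0 of them. That table was used for names only. A gene was represented by its probe set with the highest mean over all arrays among those that name it alone.

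Tests were run in R 4.3.3 with limma 3.58.1, and tables were read with the data.table package, version 1.17.8. A linear model with a mean for each of the 7 groups was fitted to all 35 arrays, so that the groups shared 1 estimate of the spread with 28 residual degrees of freedom. limma's empirical Bayes step added 5.41 prior degrees of freedom. Each concentration was compared with air, a moderated F test asked whether any group differed, and a second model fitted a slope on log2(ppm + 1). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets within a comparison, and an adjusted p under 0.05 counted as a call. Calls with a fold of at least 1.5 were counted as well. Standard errors (SE) are those of the fit, and standard deviations (SD) are over the 5 mice of a group.

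A total of 32 gene lists, with 481 different genes of which 412 were measured, covered styrene metabolism, nuclear receptor targets, stress responses, lipid and bile acid pathways, the circadian clock, sex-biased and zonated hepatocyte genes, and 9 other cell types that a piece of liver can hold. Some genes are in more than 1 list. Lists were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 32 lists. camera compares a list with all other measured genes. It was repeated with a correlation estimated for each list, which allows for genes that vary together, and with fry, which asks whether a list's genes move one way without comparing them with other genes. For each list the members that passed were counted over all probe sets and again with p adjusted over the list alone.

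The genes named in the text followed a rule. For 120 ppm and for the slope these were the 12 largest rises and 12 largest falls among genes that passed, and for the other concentrations the 6 largest each way. The rule added the 10 genes with the smallest p of the F test, up to 4 passing members of each list, every member of the styrene metabolism list, and 14 genes of drug metabolism, DNA damage, the clock and cell division. Of these 14, Cyp4a14 and the clock gene Nr1d1 had no probe set that named them alone here and were not analysed. Where fewer than 5 genes passed, the 5 with the smallest p in each direction among brighter probe sets were named as not having passed. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

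Log2 fold changes of different concentrations were correlated across probe sets. All concentrations share the same air mice, which alone gives a correlation above 0, so 100 simulated sets of unchanged groups against the same controls were drawn, and the air mice were also split between the comparisons. Single values per array, namely the array median and the difference between 3' and 5' probe sets of the actin and GAPDH transcripts, were compared with air by two-sided exact permutation tests over the 252 divisions of 10 arrays, with adjustment over 18 tests.

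The alternatives in this first set were centring each array on its median, a second quantile normalization, leaving out the dimmer probe sets, an intensity-dependent robust prior, array weights, the replicate number as a block, 1 probe set per gene, fits of only the groups compared, other dose scales, and leaving out each array in turn. For each comparison, other divisions of the same arrays were fitted too, 100 in all with the real one. The place of each mouse's number among the 8 consecutive numbers of its group, and leaving out the 2 arrays with the lowest correlation to the others, were added after the data were seen. The number was read from the sample title and taken as that of the animal. The runs of 8 numbers were inferred from the numbers seen, 5 per group.

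The fit was tested on simulated data for 120 ppm against air over 45037 probe sets. It recovered 97% of 100 probe sets changed 2-fold and 99% of 100 changed 4-fold, with 8 calls among unchanged probe sets. In these simulated data the list test called the 1 list that had been shifted and no other. On the measured arrays of 120 ppm and air, other divisions of the arrays called up to 15 lists. The simulation therefore gives no rate of false list calls for the measured arrays.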

Results

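The comparisons ask which liver transcripts differed on the morning after a single styrene exposure, at which concentration, and in which direction. Each of the 7 groups held 5 arrays, 1 per mouse, and there was no second reading of any mouse. Pearson correlations between pairs of arrays over all probe sets lay between 0.965 and 0.995. The first principal component held 27.9% of the variance. Its mean was -22.6 in air and -17.2 at 10 ppm, then 6.36 at 20 ppm, 34.2 at 40 ppm and 37.1 at 120 ppm. The arrays of 40 and 120 ppm, from 31.6 to 40.1, lay above every array of the other groups, whose highest value was 20.7.

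Some measures of the arrays themselves also moved with concentration. The array median was 3.503 ± 0.0193 (SD, n = 5) in air, 3.573 ± 0.0206 at 40 ppm and 3.598 ± 0.0273 at 120 ppm, and both differed from air (two-sided exact permutation p = 0.00794, adjusted p = 0.0286). The 3' minus 5' difference of the actin transcript, a reading of RNA integrity and labelling, was 0.479 in air on the log2 scale. It was 0.724 at 20 ppm, 0.706 at 40 ppm and 0.717 at 120 ppm (exact permutation p = 0.00794, adjusted p = 0.0286 at each). The same difference for the GAPDH transcript was 0.147 in air and 0.120 at 120 ppm, and no concentration differed from air (adjusted p = 0.505 at 120 ppm, exact permutation test). The actin probe sets were themselves lower at 120 ppm, with changes of -0.45 at the 3' end (adjusted p = 0.000195) and -0.69 at the 5' end (adjusted p = 7.79e-05) in limma over the 104 control probe sets. In the same test some bacterial controls, which read no liver transcript, were higher at 120 ppm, with BioB 5' at 0.515 (adjusted p = 0.0154). Others did not pass, such as BioDn 5' at 0.204 (adjusted p = 0.241).

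The 10 genes with the smallest p among the 7 groups included the acute phase gene Serpina3n, the clock genes Usp2 and Ciart, and the chaperone genes Hspb1 and Serpinh1. Serpina3n, a secreted protease inhibitor of the acute phase, had a mean of 10.5 in air, 11.2 at 20 ppm, 11.4 at 40 ppm and 12.4 at 120 ppm (adjusted p = 6.49e-09, F test). Usp2, a deubiquitinating enzyme with a daily rhythm in liver, had means of 5.82, 7.21, 8.18 and 8.53 in those groups (adjusted p = 6.57e-09). Hspb1, a small heat shock protein, went the other way, with 9.52 in air, 7.62 at 40 ppm and 7.42 at 120 ppm (adjusted p = 2.38e-08). Serpinh1, the collagen chaperone of the endoplasmic reticulum, had 7.14, 6.04, 5.65 and 5.53 (adjusted p = 2.61e-08). Prtn3, a protease of neutrophil granules, had 3.83 in air, 3.72 at 40 ppm and 5.26 at 120 ppm (adjusted p = 1.02e-08). The others of the 10 were Atp6v0d2, a proton pump subunit, Vegfa, the blood vessel growth factor, Ciart, a repressor of the clock, Pdhb, a subunit of pyruvate dehydrogenase, and D630004K10Rik. In all, 9177 of 45037 probe sets differed among the groups, and they named 4947 genes.

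The number of transcripts that differed from air climbed steeply between 10 and 40 ppm. At 1, 5 and 10 ppm the counts were 2, 69 and 0 probe sets, with 2534, 3189 and 2871 at an unadjusted p under 0.05 in limma. At 20 ppm 466 probe sets were called, 187 higher and 279 lower. At 40 ppm there were 6586, with 4384 higher and 2202 lower, and at 120 ppm 8727, with 5846 higher and 2881 lower. A fold of at least 1.5 was reached by 246 of the calls at 20 ppm, 1952 at 40 ppm and 2237 at 120 ppm. The excess of rises over falls at 40 and 120 ppm goes with the shift of the array median. When each array was centred on its median, the split was 148 higher and 375 lower at 20 ppm, 2712 and 3863 at 40 ppm, and 2943 and 5560 at 120 ppm. After a second quantile normalization it was 2732 and 3234 at 40 ppm, and 3570 and 4100 at 120 ppm.

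**Figure D1:**
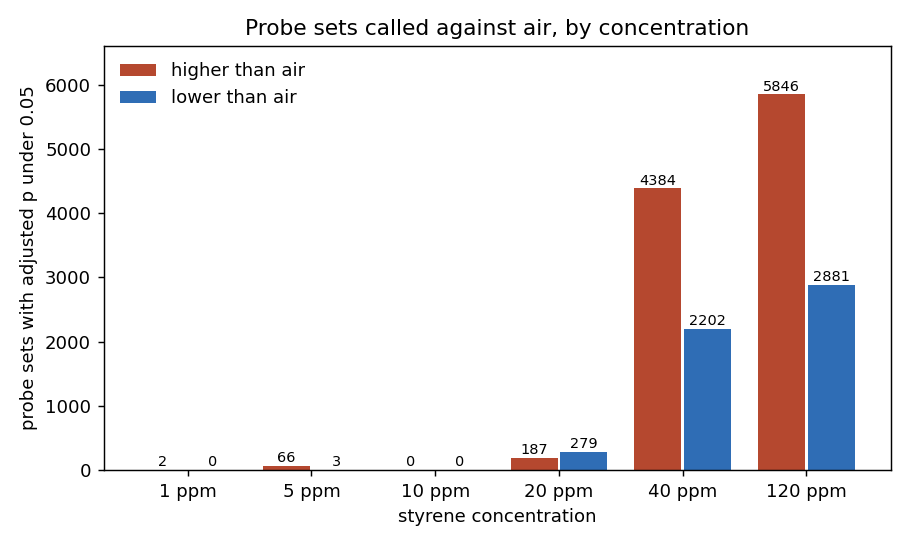
Bars give the number of probe sets higher (up) and lower (down) than in air at each styrene concentration in ppm, by limma with adjusted p under 0.05 and 5 arrays per group. The bars reach 5846 higher and 2881 lower at 120 ppm, against 0 at 10 ppm.

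At 120 ppm the 12 largest rises were those of Lcn2, Orm2, Orm3, Saa1 and Saa2, which encode acute phase proteins, of the clock genes Dbp, Ciart, Usp2 and Per3, and of Acot3, Slc16a5 and Fmo2. Lcn2, a secreted protein that binds bacterial iron carriers, rose 26.8-fold, by 4.74 ± 0.61 (SE) on the log2 scale (adjusted p = 7.12e-06). Its mean was 7.20 ± 1.17 (SD, n = 5) in air and 11.94 ± 0.20 at 120 ppm. Acot3, a peroxisomal thioesterase of long fatty acids, rose 16.8-fold from 4.33 ± 0.17 to 8.40 ± 1.02 (limma adjusted p = 0.000137), with 6.61 in 120 ppm replicate 5 far under the other mice of its group. Slc16a5, a transporter of the monocarboxylate family, rose 13.6-fold (adjusted p = 4.37e-05), and air replicate 5, at 4.25, stood apart from the other air mice. Fmo2, a flavin monooxygenase, rose 5.70-fold, by 2.51 ± 0.34 (adjusted p = 1.44e-05). Among the largest falls, the heat shock gene Hspa1b, which also fell with the animals' numbers within groups (-0.26 per place, adjusted p = 0.0111), fell by 2.82 ± 0.62 on the log2 scale (adjusted p = 0.00189) and Bcl6, a transcriptional repressor, by 2.64 ± 0.72 (adjusted p = 0.00992). Elovl3, an elongase of fatty acids with a daily rhythm, fell by 2.35 ± 0.36 (adjusted p = 5.45e-05), and its value of 10.85 in air replicate 5 stood apart from the other air mice. The tubulin genes Tubb2a and Tuba1a fell by 2.15 (adjusted p = 1.79e-05) and 1.83 (adjusted p = 7.11e-06) on the log2 scale, with Tuba1a at 6.95 in air replicate 1, apart from the rest of its group.

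**Figure D2:**
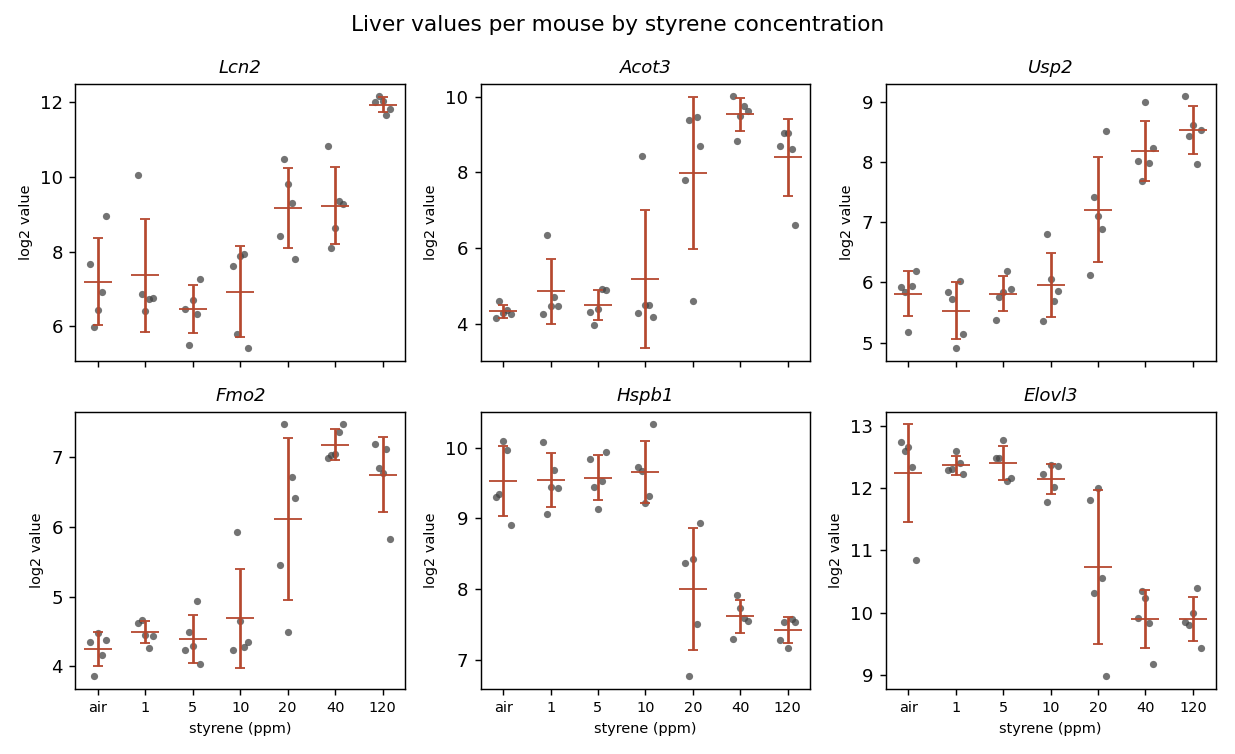
Each panel plots 1 gene, with the log2 value of each mouse as a point and the group mean ± SD over 5 mice, against styrene in ppm. Lcn2 goes from a mean of 7.20 in air to 11.94 at 120 ppm and Hspb1 from 9.52 to 7.42, while Acot3 is spread widely within its exposed groups.

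Clock genes at 120 ppm split into a higher and a lower arm. The PER arm, clock genes whose transcripts peak from the afternoon into the evening in mouse liver, had a median change of 1.66 on the log2 scale, and 9 of its 10 measured members rose, also 9 adjusted over the list alone. camera gave an adjusted p of 4.3e-09, and the adjusted p = 0.0171 with an estimated correlation. Per3, a period gene of the core clock, rose by 2.17 ± 0.39 (adjusted p = 0.00033) and Ciart by 2.77 (adjusted p = 6.79e-06). Dbp, an output transcription factor of the clock, rose by 3.46 ± 0.93 (adjusted p = 0.00899). Of the 5 measured genes of the opposite BMAL1 arm, 3 fell, also 3 adjusted over the list alone, with a median of -1.09 (adjusted p = 0.00362, and adjusted p = 0.231 with an estimated correlation). Arntl, which encodes BMAL1, fell by 1.09 ± 0.25 on the log2 scale (adjusted p = 0.00328), and Npas2, a partner of BMAL1, by 1.83 (adjusted p = 0.000458). Within groups Dbp, Per3 and Npas2 also followed the order of the animals' numbers, in the direction of their change at 120 ppm, with slopes of 0.53, 0.19 and -0.16 per place (adjusted p = 2.11e-05, 0.00203 and 0.00217). The actin 3' minus 5' difference was higher at 120 ppm as well, at 0.717 against 0.479 in air.

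Some genes of acute phase proteins, which hepatocytes secrete in inflammation, rose at 120 ppm, and most heat shock genes fell. Of 23 measured acute phase genes 12 rose and none fell, also 12 adjusted over the list alone, with a median of 0.34 (adjusted p = 1.91e-08, and adjusted p = 0.216 with an estimated correlation). Serpina3n rose by 1.85 ± 0.18 (adjusted p = 9.02e-08), and the serum amyloid gene Saa2 rose 6.82-fold (adjusted p = 0.000218). Orm2, an orosomucoid, rose by 2.50 ± 0.31 (adjusted p = 5.31e-06), and Orm3 rose 4.90-fold (adjusted p = 0.000656) with a low value of 6.38 in 120 ppm replicate 4. The Saa and Orm genes are near-identical relatives that probes can read together. Heat shock genes, the chaperones of the cytosol, had a median of -0.94, with 10 of 12 lower, or 11 adjusted over the list alone (adjusted p = 1.66e-09, and adjusted p = 0.0622 with an estimated correlation). Hspb1 fell by 2.10 ± 0.27 on the log2 scale (adjusted p = 7.12e-06) and Hsph1, a co-chaperone of HSP70, by 1.30 (adjusted p = 0.00108). Of 20 endoplasmic reticulum stress genes 5 fell, or 7 adjusted over the list alone, with a median of -0.34 (adjusted p = 0.00136, and adjusted p = 0.323 with an estimated correlation). Manf, a secreted stress protein, fell by 1.33 on the log2 scale (adjusted p = 0.000188) and Hyou1, a chaperone, by 1.06 (adjusted p = 0.000139). These groups moved with the array median, 3.598 against 3.503 in air, with the actin 3' minus 5' difference and with lower Kupffer cell markers.

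The genes of styrene metabolism moved little at 120 ppm, and those that did went both ways. Of 13 measured members, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone, with a median of -0.01 (adjusted p = 0.415). Cyp2f2, which oxidises styrene in lung and liver, fell by 0.29 ± 0.06 on the log2 scale (adjusted p = 0.00138), and Ephx1, the microsomal epoxide hydrolase that opens styrene oxide, by 0.52 ± 0.14 (adjusted p = 0.00801). Cyp2e1, the other main oxidase, rose by 0.21 ± 0.05 (adjusted p = 0.00628), a call that ended with arrays centred on their median (0.12, adjusted p = 0.141). Aldh1a1, an aldehyde dehydrogenase, rose by 0.24 (adjusted p = 0.0285) with 120 ppm replicate 5, at 12.68, apart from its group, and Gstp1, a glutathione transferase, fell by 0.20 on the log2 scale (adjusted p = 0.0333). The call of Aldh1a1 ended with centring (adjusted p = 0.2) and without any 1 of air replicates 1, 2 and 3 or 120 ppm replicates 1, 3 and 4, with an adjusted p of up to 0.0703. That of Gstp1 ended without any 1 of the air or 120 ppm replicates numbered 1, 2 and 3, with an adjusted p of up to 0.0929. Gstm1 had a change of -0.20 (adjusted p = 0.155) and Gstt1 one of -0.28 (adjusted p = 0.0634), and both passed with centring, at -0.29 (adjusted p = 0.0297) and -0.37 (adjusted p = 0.0168). Gstt1 passed with the intensity-dependent prior (0.044) and with array weights (0.0361) as well. Ephx2 had 0.09 (adjusted p = 0.418), Mgst1 0.06, with 120 ppm replicate 2 at 13.45 apart from its group, Adh1 0.00, Adh4 -0.02, Aldh2 -0.01 and Aldh3a2 0.24 (adjusted p = 0.255).

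Antioxidant and drug metabolism genes at 120 ppm did not share a direction. Of 29 measured targets of NRF2, the regulator of the antioxidant response, 3 rose and 13 fell, or 4 and 13 adjusted over the list alone, with a median of -0.25 (adjusted p = 1.91e-05, and adjusted p = 0.216 with an estimated correlation). Gsta4, a glutathione transferase, fell by 1.04 ± 0.14 on the log2 scale (adjusted p = 1.73e-05), and Gstm3, another, by 1.25 (adjusted p = 0.00649). Nqo1, a quinone reductase, had 0.50 (adjusted p = 0.0516), and passed among the brighter probe sets (0.0464), with the intensity-dependent prior (0.0486), with array weights (0.035), without the 2 least correlated arrays (0.0378) and in a fit of only the groups compared (0.0388). Of 24 targets of CAR and PXR, the receptors that induce drug metabolism, 6 rose and 2 fell (adjusted p = 0.107, and 0.0232 with arrays centred on their median and 0.0465 by fry). Among them Cyp2b10 had 0.33 (adjusted p = 0.699) and Cyp3a11 0.24 (adjusted p = 0.45), while Cyp3a13, another cytochrome P450, rose by 1.32 (adjusted p = 0.000187). Cyp1a2, a P450 of the AhR pathway, fell by 0.67 on the log2 scale (adjusted p = 6.92e-05) and Cyp1a1 had -0.39 (adjusted p = 0.0873). Cyp1a1 passed with centring, at -0.49 (adjusted p = 0.031), after a second quantile normalization (0.0409), with array weights (0.0463) and in a fit of only the groups compared (0.0394). The p53 targets Phlda3 and Ccng1 rose by 0.46 and 0.37, the latter not with centring (0.28, adjusted p = 0.0907), and Cdkn1a, the cell cycle inhibitor, had -0.54 (adjusted p = 0.583).

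At 120 ppm some genes of fatty acid synthesis fell and some targets of PPARA rose. Of 17 genes of fatty acid synthesis 4 fell, also 4 adjusted over the list alone, with a median of -0.32 (adjusted p = 0.000592, and adjusted p = 0.252 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, fell by 1.03 ± 0.21 on the log2 scale (adjusted p = 0.001) and Me1, the malic enzyme that makes NADPH, by 0.98 (adjusted p = 0.000477). Of 25 targets of PPARA, the receptor that drives fatty acid oxidation, 11 rose and 2 fell, or 11 and 4 adjusted over the list alone, but the list did not pass (adjusted p = 0.255). Cpt1a, the carnitine transferase that lets fatty acids into mitochondria, rose by 0.82 ± 0.16 (adjusted p = 0.000565). Of 19 genes of cholesterol synthesis 5 rose and none fell (adjusted p = 0.107, and 0.0232 with centring), and Hsd17b7 rose by 0.98 (adjusted p = 0.000477). Among glucocorticoid targets 5 of 13 rose (adjusted p = 0.323), and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.99 ± 0.29 (adjusted p = 3.69e-05). The actin 3' minus 5' difference and the array median were higher at 120 ppm too, at 0.717 and 3.598 against 0.479 and 3.503 in air.

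Sex-biased and proliferation genes also differed at 120 ppm. Of 11 genes higher in male liver 6 fell, or 8 adjusted over the list alone, with a median of -0.53 (adjusted p = 4.6e-05, and adjusted p = 0.216 with an estimated correlation). Hsd3b5, a steroid dehydrogenase of male liver, fell by 1.45 on the log2 scale (adjusted p = 0.00575). Of 11 genes higher in female liver 4 rose, or 5 adjusted over the list alone, with a median of 0.38 (adjusted p = 0.00362, and adjusted p = 0.216 with an estimated correlation). Cyp2b9, a female-biased P450, rose by 0.86 (adjusted p = 0.00845). Of 22 cell cycle genes 2 rose and 7 fell, also 2 and 7 adjusted over the list alone, with a median of -0.09 (adjusted p = 0.0365). That list call gave adjusted p = 0.441 with an estimated correlation and ended with arrays centred on their median (adjusted p = 0.0747) and by fry (adjusted p = 0.0972). Ccnd1, the G1 cyclin, fell by 1.21 on the log2 scale (adjusted p = 0.00776) and Mcm2, of the replication helicase, by 0.68 (adjusted p = 0.00254), while Mki67 had 0.18 (adjusted p = 0.291). These lists moved along with the actin 3' minus 5' difference, 0.717 against 0.479 in air, and with lower Kupffer cell markers.

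Markers of other cell types changed at 120 ppm as well. Of 11 markers of Kupffer cells, the resident macrophages, 6 fell, or 8 adjusted over the list alone, with a median of -0.53 (adjusted p = 1.61e-05, and adjusted p = 0.259 with an estimated correlation). Clec4f, a lectin of Kupffer cells, fell by 0.74 on the log2 scale (adjusted p = 0.000426) and C1qa, a complement subunit, by 0.68 (adjusted p = 0.00101). Of 11 stellate cell and fibroblast markers 2 fell, also 2 adjusted over the list alone, with a median of -0.15 (adjusted p = 0.0296, and adjusted p = 0.259 with an estimated correlation), a call that ended among the brighter genes alone (adjusted p = 0.0564). Col3a1, a fibrillar collagen, fell by 1.41 on the log2 scale (adjusted p = 0.00114). The exocrine pancreas list did not pass (adjusted p = 0.296), but its member Cela1, an elastase, fell by 1.10 on the log2 scale (adjusted p = 5.45e-05). The surfactant gene Sftpc, of lung, fell by 1.82 on the log2 scale (adjusted p = 0.00553, and 0.0548 in a fit of only the groups compared). Its highest value was in air replicate 4, without which the change was -1.15 (adjusted p = 0.0205). The remaining lists did not pass at 120 ppm, with an adjusted p of 0.482 for AhR, 0.128 for p53 (0.00143 by fry), 0.96 for bile acids, 0.748 for gluconeogenesis, 0.107 for interferon and 0.62 for immediate early genes. It was 0.889 for pericentral and 0.823 for periportal genes, and 0.173 for endothelial, 0.23 for cholangiocyte, 0.78 for lymphocyte, 0.889 for neutrophil, 0.484 for erythroid and 0.889 for adipocyte markers. For AhR targets, bile acid, pericentral and periportal genes and neutrophil markers the median lay above 0, at 0.03, 0.07, 0.06, 0.15 and 0.04, while camera's direction was down.

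At 40 ppm most genes of the PER arm of the clock rose, as did some PPARA targets and some genes of cholesterol synthesis. Acot3 rose 37.0-fold, by 5.21 ± 0.68 (adjusted p = 1.16e-05), Slc16a5 18.6-fold (adjusted p = 1.53e-05) and Fmo2 7.66-fold (adjusted p = 2.84e-06). The PER arm had a median of 1.498, and 9 of 10 rose, also 9 adjusted over the list alone (adjusted p = 9.21e-10, and adjusted p = 0.00978 with an estimated correlation). Per3 rose by 2.48 (adjusted p = 0.000103) and Usp2 by 2.36 (adjusted p = 1.11e-05), while Npas2 fell by 1.97 on the log2 scale (adjusted p = 0.000267). Of 25 PPARA targets 11 rose, or 12 with 1 lower adjusted over the list alone, with a median of 0.50 (adjusted p = 2.57e-05, and adjusted p = 0.370 with an estimated correlation). Cpt1a rose by 0.99 (adjusted p = 0.000101) and Vnn1, a pantetheinase, by 1.61 (adjusted p = 0.00167). Of 19 cholesterol synthesis genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.558 with an estimated correlation), and the list was not called by fry (adjusted p = 0.0747). Lss, which closes the sterol rings, rose by 1.26 (adjusted p = 0.00592). Dbp rose by 3.34 (adjusted p = 0.0143), a call that ended without air replicate 3 (adjusted p = 0.0532).

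Lower groups at 40 ppm included heat shock genes, with a median of -0.63 and 6 of 12 lower, or 9 adjusted over the list alone (adjusted p = 2.49e-05, and adjusted p = 0.304 with an estimated correlation). Hspb1 fell by 1.91 on the log2 scale (adjusted p = 3.25e-05). Of 29 NRF2 targets 4 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.000465, and adjusted p = 0.304 with an estimated correlation), with Gsta4 at -0.94 (adjusted p = 8.2e-05). Fatty acid synthesis had a median of -0.21 with 4 of 17 lower, also 4 adjusted over the list alone (adjusted p = 0.00339, and adjusted p = 0.370 with an estimated correlation), and Acacb fell by 1.20 on the log2 scale (adjusted p = 0.000307). Endoplasmic reticulum stress genes had a median of -0.25 with 6 of 20 lower, or 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.003, and adjusted p = 0.387 with an estimated correlation), and Pdia6, a disulphide isomerase, fell by 0.85 on the log2 scale (adjusted p = 0.000164). The other lists called were the BMAL1 arm, male-biased genes and cell cycle genes, which were lower, with adjusted p = 0.003, 0.00187 and 0.0102, and female-biased genes and CAR and PXR targets, which were higher, with 0.000563 and 0.0298. Their adjusted p = 0.304, 0.370, 0.370, 0.241 and 0.444, in that order, with an estimated correlation. In the BMAL1 arm 3 of 5 fell, also 3 adjusted over the list alone; of 11 male-biased genes 1 rose and 2 fell, or 1 and 6; of 22 cell cycle genes 1 rose and 4 fell under both adjustments. Of 11 female-biased genes 5 rose, or 6 adjusted over the list alone, and of 24 CAR and PXR targets 8 rose and 2 fell, or 9 and 2, a list call that ended among the brighter genes alone (adjusted p = 0.151). Kupffer cell markers had a median of -0.37 with 4 of 11 lower, or 6 adjusted over the list alone (adjusted p = 0.000465, and adjusted p = 0.387 with an estimated correlation), and Clec4f fell by 0.57 on the log2 scale (adjusted p = 0.00521). Exocrine pancreas markers had a median of -0.08 with 2 of 7 lower, also 2 adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.353 with an estimated correlation), a call that ended with centring (adjusted p = 0.0604), and Cela1 fell by 1.12 on the log2 scale (adjusted p = 6.47e-05). These groups moved with an actin 3' minus 5' difference of 0.706 and an array median of 3.573, against 0.479 and 3.503 in air. For styrene metabolism 3 of 13 rose and the list did not pass (adjusted p = 0.902). Cyp2e1, with 0.22 (adjusted p = 0.00647), was among the 3, a call that ended with centring (adjusted p = 0.0711).

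At 20 ppm fewer genes differed than at 40 ppm, and they included genes of lipid metabolism, the clock and chaperones. Acot3 rose 12.7-fold (adjusted p = 0.00762) and Fmo2 3.65-fold, by 1.87 ± 0.34 (adjusted p = 0.00762), each in 5 of 5 mice above every air mouse. Npas2 fell by 1.86 ± 0.34 on the log2 scale (adjusted p = 0.00762), Hspb1 by 1.52 ± 0.27 (adjusted p = 0.00707), Acacb by 1.08 ± 0.21 (adjusted p = 0.00971) and Gsta4 by 0.84 ± 0.14 (adjusted p = 0.00613). The PER arm had a median of 1.12 with 4 of 10 higher, or 9 adjusted over the list alone (adjusted p = 1.56e-10, and adjusted p = 0.00636 with an estimated correlation). Fatty acid synthesis had a median of -0.50 with 3 of 17 lower, or 9 adjusted over the list alone (adjusted p = 1.59e-09, and adjusted p = 0.0491 with an estimated correlation). PPARA targets had a median of 0.37 with 5 of 25 higher, or 12 adjusted over the list alone (adjusted p = 6.39e-10, and adjusted p = 0.154 with an estimated correlation). Fkbp5 rose by 1.46 (adjusted p = 0.0127) and Cpt1a by 0.80 (adjusted p = 0.00991). The lung genes Scgb1a1 and Sftpc fell by 2.51 (adjusted p = 0.0241) and 2.10 (adjusted p = 0.0177) on the log2 scale. Both were highest in air replicate 4, without which the changes were -1.82 (adjusted p = 0.0891) and -1.43 (adjusted p = 0.0439).

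Further lists called at 20 ppm were NRF2 targets (median -0.14, adjusted p = 1.02e-05), interferon response (-0.29, adjusted p = 0.000319), heat shock (-0.36, adjusted p = 0.000518), the BMAL1 arm (-0.66, adjusted p = 0.000889), male-biased genes (-0.38, adjusted p = 0.006) and cell cycle (-0.09, adjusted p = 0.0243). Their adjusted p = 0.154, 0.373, 0.267, 0.154, 0.373 and 0.373, in that order, with an estimated correlation. The members lower were 6 of 29, 1 of 19, 1 of 12, 2 of 5, 1 of 11 and 1 of 22, and 9, 1, 3, 2, 4 and 2 adjusted over the list alone, where 1 NRF2 target and 1 male-biased gene were higher. Female-biased genes (0.16, adjusted p = 0.002) and acute phase genes (0.11, adjusted p = 0.0265) were called as higher, with adjusted p = 0.154 and 0.659 with an estimated correlation. Of 11 female-biased genes 2 rose, or 3 adjusted over the list alone, while no acute phase gene passed over all probe sets in limma and 4 of 23 were higher adjusted over the list alone. Kupffer cell markers had a median of -0.45, with none of 11 passing over all probe sets in limma and 5 lower adjusted over the list alone (adjusted p = 3.45e-06, and adjusted p = 0.267 with an estimated correlation), and exocrine pancreas markers one of -0.13 with 2 of 7 lower, also 2 adjusted over the list alone (adjusted p = 0.0496, and adjusted p = 0.267 with an estimated correlation), a call that ended with centring (adjusted p = 0.0622) and with the replicate number as a block (adjusted p = 0.0565). fry did not call Kupffer cell, exocrine pancreas and heat shock genes (adjusted p = 0.0565 each), interferon (0.119), male-biased and cell cycle genes (0.133 each) or acute phase genes (0.394). The actin 3' minus 5' difference of this group was 0.724, against 0.479 in air. Single arrays weighed heavily: the count of 466 became 37 without 20 ppm replicate 2, 88 without replicate 4, 163 without replicate 5 and 1109 without replicate 3. It became 227, 154 and 233 without air replicate 2, 3 or 4, and a fit of only the groups compared called 0, with 5343 at an unadjusted p under 0.05 in limma. Among the genes named at 20 ppm, the calls of Acot3 (adjusted p = 0.0541), Fkbp5 (0.0711) and Cpt1a (0.0641) ended without 20 ppm replicate 2, that of Sftpc without replicate 2 (0.0856) or 4, and that of Scgb1a1 without either of these (up to 0.0911) or without air replicate 2 or 4.

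At 1, 5 and 10 ppm few transcripts differed from air. At 5 ppm 66 probe sets were higher and 3 lower, and they named 20 genes. Tra2b, a splicing factor, rose by 0.61 ± 0.10 (adjusted p = 0.00366), Brwd1, a chromatin protein, by 0.64 (adjusted p = 0.018) and Dr1, a repressor of transcription, by 0.49 (adjusted p = 0.0147). Blvra, a biliverdin reductase, fell by 0.42 on the log2 scale (adjusted p = 0.0296). Of the 9 genes the naming rule took, only Tra2b passed without any 1 array, and its call ended in a fit of only the groups compared (adjusted p = 0.181). Without 5 ppm replicate 3 the adjusted p was 0.102 for Brwd1, 0.0823 for Dr1 and 0.114 for Blvra. The count of 69 became 22 without that array, 30 without 5 ppm replicate 2, 114 without replicate 1, 120 without replicate 5, and 43, 29, 30 and 42 without air replicate 2, 3, 4 or 5. At 1 ppm the 2 calls were probe sets with no gene name here, higher by 0.45 ± 0.08 (adjusted p = 0.0216) and 0.80 ± 0.12 (adjusted p = 0.00945), and leaving out 1 array gave between 0 and 6. Pparg, the fat cell receptor, had -0.68 at 1 ppm (adjusted p = 0.254), and at 10 ppm Apob, the main protein of liver lipoproteins, had 0.59 (adjusted p = 0.33) and Tra2b 0.44 (adjusted p = 0.277).

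Gene lists at these concentrations had small medians. NRF2 targets had -0.15 at 1 ppm (adjusted p = 0.000454, and adjusted p = 0.642 with an estimated correlation). At 5 ppm the PER arm had 0.29 (adjusted p = 0.0482), pericentral hepatocyte genes 0.10 (adjusted p = 0.00938), acute phase genes -0.16 (adjusted p = 0.00656) and Kupffer cell markers -0.18 (adjusted p = 0.0047), each with adjusted p = 0.913 with an estimated correlation. At 10 ppm the PER arm had 0.40 (adjusted p = 0.00733), endoplasmic reticulum stress genes 0.23 (adjusted p = 0.00733) and heat shock genes 0.21 (adjusted p = 0.0307), each with adjusted p = 0.9995 with an estimated correlation. No member of these lists passed over all probe sets in limma, and adjusted over the list alone 1 pericentral gene did at 5 ppm. The medians of the heat shock and endoplasmic reticulum stress genes at 10 ppm have the opposite sign from those of the same lists at 120 ppm. So does the median of the acute phase genes at 5 ppm. The difference between the concentrations was not tested by list.

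**Figure D3:**
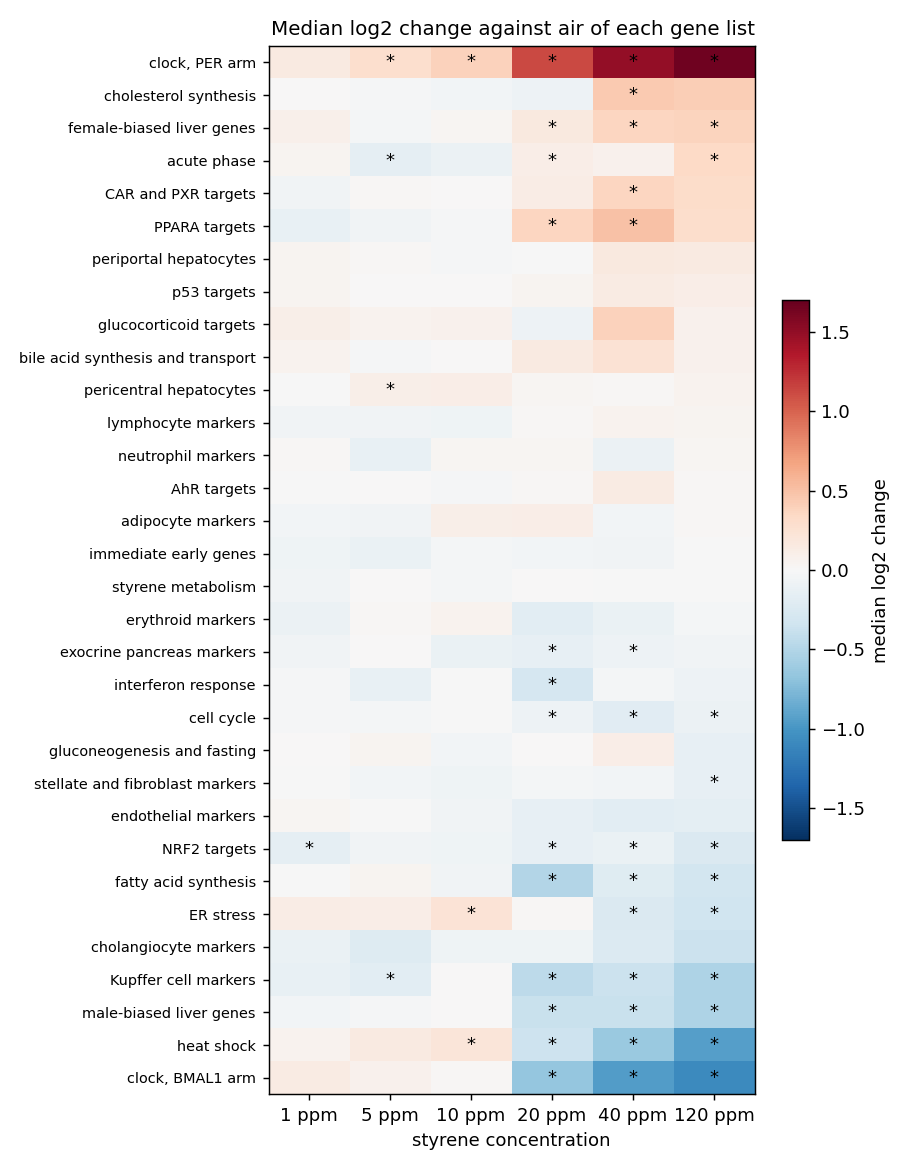
Colour gives the median log2 change from air of each of 32 gene lists (vertical axis) at each styrene concentration in ppm (horizontal axis), and a star marks an adjusted p under 0.05 in camera with the preset correlation. The PER arm of the clock goes from 0.29 at 5 ppm to 1.66 at 120 ppm, and heat shock genes reach -0.94 there.

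In the slope fitted over all concentrations, the steepest rises included clock and acute phase genes and the steepest falls included heat shock genes. A called slope does not show a change at each step and can come from the higher concentrations alone. Against air 2, 69 and 0 probe sets were called at 1, 5 and 10 ppm, and 11 between 120 and 40 ppm. The actin 3' minus 5' difference and the array median were also higher at 120 ppm, at 0.717 and 3.598 against 0.479 and 3.503 in air. Per unit of log2(ppm + 1), Acot3 rose by 0.77 (adjusted p = 3.33e-06), Lcn2 by 0.65 (adjusted p = 1.26e-05), Usp2 by 0.46 (adjusted p = 6.72e-08) and Fmo2 by 0.45 (adjusted p = 4.88e-07). Trim24, a transcriptional cofactor, rose by 0.37 (adjusted p = 1.25e-06), and Mt1, a metallothionein that binds zinc and copper, by 0.36 (adjusted p = 0.000764). Hspa1b fell by 0.48 (adjusted p = 0.000104), Elovl3 by 0.42 (adjusted p = 1.35e-06), and Tubb2a and Hspb1 by 0.36 each (adjusted p = 9.37e-07 and 1.11e-06). Among lists, the PER arm had a median slope of 0.26 with 9 of 10 higher, or 10 adjusted over the list alone (adjusted p = 4.46e-09, and adjusted p = 0.0351 with an estimated correlation). Heat shock genes had -0.15 with 10 of 12 lower, also 10 adjusted over the list alone (adjusted p = 1.32e-08, and adjusted p = 0.220 with an estimated correlation). In all 14 lists were called, and 1 with an estimated correlation. Among the others 13 of 23 acute phase genes were higher, also 13 adjusted over the list alone (adjusted p = 0.000246, and adjusted p = 0.458 with an estimated correlation), and 8 of 17 fatty acid synthesis genes lower, or 9 adjusted over the list alone (adjusted p = 0.000154, and adjusted p = 0.255 with an estimated correlation). A slope was called for 14414 probe sets, 9541 higher and 4873 lower, but for 5345 and 8810 with arrays centred on their median, and for 6387 and 6859 after a second quantile normalization. Dmbt1, a secreted mucosal protein, fell by 0.32, a call that ended with ppm on a linear scale (limma adjusted p = 0.185) and without air replicate 4 (adjusted p = 0.0535).

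Between the higher concentrations, in a comparison added after the data were seen, the genes higher at 120 ppm than at 40 ppm included Orm2, Prtn3 and Serpina3n. Orm2 differed by 2.42 ± 0.31 (adjusted p = 0.000112), Prtn3 by 1.54 ± 0.14 (adjusted p = 8.07e-08) and Serpina3n by 1.01 ± 0.18 (adjusted p = 0.0153). Lcn2, with 2.70 ± 0.61, did not pass (adjusted p = 0.162), nor did Saa2 (1.74, adjusted p = 0.394) or Acot3 (-1.14, adjusted p = 0.963). In all 11 probe sets were called, each higher at 120 ppm, with 2513 at an unadjusted p under 0.05. Between 40 and 20 ppm, also compared outside the plan, 168 probe sets were called, 122 higher and 46 lower at 40 ppm.

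The calls of different concentrations overlapped, as groups set against the same air mice do in part by construction. Of the rises at 40 ppm 3323 were also rises at 120 ppm, where 569.1 would be shared with no relation, and of the falls 1576, against 140.9, with 0 in opposite directions. For 20 and 120 ppm 171 rises and 227 falls were shared, against 24.27 and 17.85. Across probe sets, which are not independent, the log2 changes at 120 ppm correlated with those at 1, 5, 10, 20 and 40 ppm with r = 0.363, 0.282, 0.364, 0.758 and 0.8995. Simulated unchanged groups against the shared air mice gave means of 0.516, 0.493, 0.474, 0.493 and 0.487, and highest values of 0.831, 0.812, 0.759, 0.829 and 0.824. Only the value of 40 ppm lay above its highest simulated one. In the simulation 120 ppm was unchanged as well, so the shared air mice weighed more in each correlation than in the data. The highest simulated values are therefore no limit for the measured r at 20 ppm. With separate air mice for each side, r was 0.110, 0.0582, 0.119, 0.506 and 0.708. The covariance of the changes exceeded the simulated mean by 0.00469, 0.00267, 0.00624, 0.0350 and 0.0693.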

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

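All tests of explanations in this part, the other divisions of the arrays included, were chosen after the results they address had been seen.

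Of the clock genes higher at 120 ppm, the PER arm had a median change of 1.66 on the log2 scale. The place of each mouse's number within its group might reflect the order of killing. With the place as a covariate the median was 1.498 (camera adjusted p = 5.72e-11), so that place does not account for the whole rise. The places were 1, 2, 3, 6 and 8 in air and 1, 4, 5, 6 and 8 at 120 ppm. They were so alike that the covariate could remove little, and it does not test an hour that differs between groups. Per1 changed by -0.12 ± 0.03 per place, against its rise at 120 ppm. Over the 8727 probe sets called at 120 ppm, the change correlated with the slope on the place within groups with r = 0.402. Within groups Dbp, Nr1d2, Tef and Per3 rose with the place (adjusted p = 2.11e-05, 1.22e-05, 0.000475 and 0.00203) and Npas2, Nfil3 and Cry1 of the BMAL1 arm fell (0.00217, 0.00272 and 0.0236), while Ciart, Usp2, Hlf and Per2 did not pass for a slope (0.932, 0.684, 0.844 and 0.899). A later hour of the morning or another day of killing for the high concentrations therefore cannot be told apart from an effect of styrene on the clock, which stays open and untested: the protocol puts every killing on the morning after exposure, but the hour and the day are not given in the sources used here and each group holds its own run of animal numbers.

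The lung genes Scgb1a1 and Sftpc were lower in exposed mice than in air. A candidate explanation is lung tissue or lung RNA in an air sample: 6 of 8 other lung markers, in a list written after the data were seen, had their highest value of all 35 arrays in air replicate 4 by margins from 3.503 against 3.459 for Cldn18 to 5.466 against 3.634 for Scgb3a2, where Scgb1a1 reached 9.34 against 6.89 in the next array and Sftpc 7.98 against 5.68. A fall that grows with styrene is argued against by the change from the mean of 1, 5 and 10 ppm to 120 ppm, 0.183 on average, with 0.39 for Scgb1a1 (95% interval -0.57 to 1.34) and -0.02 for Sftpc (-0.77 to 0.73). Without air replicate 4 Sftpc still passed at 20, 40 and 120 ppm, with -1.43, -1.17 and -1.15 (adjusted p = 0.0439, 0.0234 and 0.0205), and Scgb1a1 did not, with -1.82, -0.98 and -1.005 (0.0891, 0.21 and 0.169), so that array is not shown to be the only source, and a fall at every concentration alike stays open.

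At 5 ppm 66 probe sets were higher than in air, by a median of 0.745. Choosing probe sets for a difference to these air mice raises them at 1 and 10 ppm too, where their medians were 0.433 and 0.430, so the share of the difference to air that lay above 1 and 10 ppm, 0.348, was set against regroupings of the same 20 arrays with probe sets chosen the same way. The other regroupings had shares of 0.261 to 0.815 with a median of 0.564, and 3 of 100, the real one included, had a share as low, which argues against a change particular to 5 ppm as the whole of the pattern. The 66 probe sets also had medians of 0.299, 0.497 and 0.5495 at 20, 40 and 120 ppm. Of them 6, 49 and 51 were called higher there too, against 0.274, 6.425 and 8.567 with no relation. The shared air mice raise these values as well. For the mean of 1, 5 and 10 ppm against air 47 probe sets were called, 45 of them higher, 38 of these shared with the 5 ppm calls, and 49, 38, 15, 13 and 26 were called without air replicate 1, 2, 3, 4 and 5. Air arrays that stand apart for a reason other than styrene cannot be told apart from a response to any low concentration, because there was 1 air group.

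Other divisions of the same arrays were set against the real count, 100 per comparison with the real one. For 5, 40 and 120 ppm, the F test and the slope only the real division, 1 of 100, called as many probe sets. That is the smallest share this test can give, over several comparisons, so chance is made unlikely there but is not excluded. At 5 ppm a fit of only the groups compared called 1. At 1 and 20 ppm the divisions with as many calls were 2 of 100, a share under 0.05. Another division called as many at 1 ppm and more at 20 ppm. The real counts and the highest of the other divisions were 2 and 2 at 1 ppm, 69 and 24 at 5 ppm, 466 and 528 at 20 ppm, 6586 and 188 at 40 ppm, 8727 and 713 at 120 ppm, 9177 and 259 for the F test, and 14414 and 5 for the slope. At 10 ppm, with 0 calls, all 100 divisions necessarily gave as many, the highest other being 5, and the count says nothing about chance. For the number of called lists chance cannot be excluded at 1 ppm (98 divisions with at least 1 list, highest 12), 5 ppm (59 with at least 4, highest 13), 10 ppm (86 with at least 3, highest 12) and 120 ppm (11 with at least 12, highest 15). The share was under 0.05 at 20 ppm (3 with at least 13), at 40 ppm (2 with at least 14) and for the slope (2 with at least 14), but there too another division called as many lists, 13, 14 and 14. At 1, 5 and 10 ppm other divisions called several times the real number of lists, and the cause was not tested.

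Single arrays stood far from the 4 others of their group by the size of their gap, which chance gives in about 1 of 20 groups tested, over 96 pairs of gene and group and 35 pairs of array measure and group. The mean correlation with the other arrays was low in 1 ppm replicate 4 (0.9861), 5 ppm replicate 1 (0.9754) and 10 ppm replicate 2 (0.9831), and high in 40 ppm replicate 3 (0.9884). The GAPDH 3' minus 5' difference was -0.402 in 20 ppm replicate 5. Among named genes the values were 6.61 for Acot3 in 120 ppm replicate 5, 12.682 for Aldh1a1 in 120 ppm replicate 5, 13.451 for Mgst1 in 120 ppm replicate 2 and 6.382 for Orm3 in 120 ppm replicate 4. In air they were 10.854 for Elovl3 and 4.25 for Slc16a5 in replicate 5, and 6.952 for Tuba1a in replicate 1.

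Of the 104 control probe sets, which the comparisons did not use, 12 were higher at 120 ppm than in air. The bacterial controls BioB, BioC and BioDn were higher by 0.433 (BioB 3'), 0.515 (BioB 5'), 0.391 (BioB middle), 0.423 (BioC 3'), 0.385 (BioC 5'), 0.324 (BioDn 3') and 0.334 (a second BioC 3') on the log2 scale, and the Cre 5' control by 0.182. The bacterial controls read no liver transcript, so their rise is not a change of liver expression, and its cause was not tested. Other bacterial control probe sets did not pass. The mouse pyruvate carboxylase controls were higher by 0.408, 0.533 and 0.409, and a repeat element control by 0.246. Another 6 control probe sets were lower at 120 ppm. These were the beta-actin sets, by -0.453 (3'), -0.584 (middle) and -0.691 (5'), TagA by -0.432, the middle TagIN set by -0.315 and a nonspecific control by -0.09.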

How the results depend on the processing

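The fits without the 2 least correlated arrays and with the place of the animal number were chosen after the data were seen. No named gene that was called reversed its direction in any setting, nor did a called list in the settings that kept every group at full size or left out the 2 arrays. The other called probe sets were not checked for direction 1 by 1. The balance of higher and lower calls did turn. At 120 ppm it went from 5846 and 2881 to 2943 and 5560 with centring, and to 3570 and 4100 after a second quantile normalization. Of the named gene results under other settings, 4114 kept their side of the threshold, 18 newly passed and 156 no longer passed; of list results 1682, 19 and 91; of gene results without 1 array 6831, 9 and 475. Where no reason is given, the cause was not tested. Detection above background was not determined for each probe set. The nonspecific control probe sets had means from 1.97 to 3.79, apart from the highest at 6.17. The median of all probe set means was 3.518, so many dimmer probe sets lie near these controls. Of the calls, 5496 of 8727 at 120 ppm and 4539 of 6586 at 40 ppm lay above that median, and the others were dimmer. Same-numbered replicates, which follow the order of the animals' numbers, were slightly more alike than others, and whether they pair was not tested. Of 30 pairs with air 14 had a correlation of residuals over 0.1. The range was -0.2142 to 0.4517, and the pairs of replicate 5 lay from 0.0996 to 0.4517. Over all groups the mean was 0.0521 against -0.0112 for other numbers, and 10 of 35 arrays were closest to an array of their own replicate number. With the number as a block the calls were 3, 78, 0, 536, 6687 and 8746 from 1 to 120 ppm, 14302 for the slope and 9031 for the F test, and 1, 4, 3, 12, 14, 12 and 14 lists.

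A second quantile normalization called 4 at 10 ppm. The brighter probe sets alone, which are fewer, gave 6 at 10 ppm, 5767 at 120 ppm and 8890 for the slope. The intensity-dependent robust prior gave 1 at 1 ppm. Array weights gave 10, 217, 7 and 1037 at 1, 5, 10 and 20 ppm. With 1 probe set per gene, so fewer tested, the counts were 0 and 1 at 1 and 5 ppm (881 and 996 at an unadjusted p under 0.05 in limma), 2590 and 3245 at 40 and 120 ppm, 5664 for the slope and 3746 for the F test. Without the 2 least correlated arrays they were 154, 5 and 771 at 5, 10 and 20 ppm. Fits of only the groups compared, with 8 residual degrees of freedom, called 0, 1 and 0 at 1, 5 and 20 ppm, with 2902, 2711 and 5343 at an unadjusted p under 0.05.

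For lists, the estimated correlation called 0, 0, 0, 2, 1, 1 and 1 at 1, 5, 10, 20, 40 and 120 ppm and for the slope, with 2, 1 and 1 at an unadjusted p under 0.05 at the first 3. fry called 0, 0, 0 and 6 from 1 to 20 ppm, with 2, 2 and 1 unadjusted at the first 3. The mean of all probe sets of a gene gave 2 lists at 1 ppm, and leaving out the 2 arrays gave 1 at 5 ppm and 0 at 10 ppm. With air mice divided between the sides, the correlation with 120 ppm was 0.1095, 0.0582, 0.1188, 0.5055 and 0.7078 for 1, 5, 10, 20 and 40 ppm.

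Without any 1 array the calls ranged from 0 to 6 at 1 ppm, 22 to 120 at 5 ppm, 0 to 2 at 10 ppm, 37 to 1109 at 20 ppm, 4397 to 6226 at 40 ppm, 6048 to 8115 at 120 ppm, 12861 to 14908 for the slope and 7934 to 9706 for the F test. Called lists ranged from 1 to 4, 1 to 6, 0 to 3, 10 to 13, 12 to 15 and 11 to 13 from 1 to 120 ppm and 12 to 16 for the slope. The correlations with 120 ppm ranged from 0.2719 to 0.4689, 0.1357 to 0.4474, 0.2792 to 0.4675, 0.69 to 0.7929 and 0.8808 to 0.9108. At 1 ppm the count was 6 without air replicate 2, 0 without air replicate 4 or 1 ppm replicate 2 or 4, and 1 without air replicate 1, 3 or 5 or 1 ppm replicate 1 or 5; at 10 ppm it was 2 without air replicate 1 or 10 ppm replicate 2. Lists at 1 ppm were 4 without air replicate 3, 3 without air replicate 1 or 5 or 1 ppm replicate 5, and 2 without air replicate 2 or 4 or 1 ppm replicate 1 or 4. At 5 ppm they were 1 without 5 ppm replicate 1 and 2 without air replicate 2 or 5 or 5 ppm replicate 5, and at 10 ppm 1 without air replicate 5 or 10 ppm replicate 1 and 0 without 10 ppm replicate 2. Of the named genes called, 8 of 9 at 5 ppm, 30 of 36 at 20 ppm, 35 of 88 at 40 ppm, 29 of 105 at 120 ppm and 5 of 121 for the slope no longer passed without some 1 array.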

Other observations

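The fit on the place of the animal number below was chosen after the data were seen.

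Further genes also differed at 120 ppm, and all but Csad below are members of lists that did not pass as a whole. Sult1d1, a sulphotransferase among the CAR and PXR targets, rose by 1.27 (adjusted p = 0.00781), and Akr1d1, a reductase of bile acid and steroid synthesis, by 1.04 (adjusted p = 0.0101). Nr1h4, which encodes the bile acid receptor FXR, rose by 0.89 (adjusted p = 0.00104), and Stard4, a carrier of cholesterol, by 0.75 (adjusted p = 0.00327). Igfbp1, a binding protein of insulin-like growth factors that insulin represses, fell by 1.55 on the log2 scale (adjusted p = 0.00717). Cdh1, the epithelial cadherin that is higher in periportal hepatocytes, fell 3.25-fold (adjusted p = 4.81e-05), and Csad, an enzyme of taurine synthesis that is in no list here, fell by 1.83 on the log2 scale (adjusted p = 0.00391). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 1.45 (adjusted p = 0.202).

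Some genes followed the place of the animal number among the 8 of its group. A total of 1173 probe sets had a slope on the place in a fit that held the group means, 680 rising and 493 falling, and 237 of them were also called at 120 ppm. Dbp, the clock output factor, had a slope of 0.53 ± 0.07 per place (adjusted p = 2.11e-05). Across air and 1, 5 and 10 ppm its mean was 3.50 in the 10 mice of places 1 to 3, with a range of 2.80 to 5.49, and 6.72 in the 8 mice of places 5 to 8, with a range of 5.74 to 7.55. In place 4, 5 ppm replicate 3 had 3.425 and 10 ppm replicate 3 had 3.792. The 20 ppm mice ranged from 4.283 in place 1 to 8.766 in place 8, with 7.238 in place 2. The 10 mice of 40 and 120 ppm had values from 7.06 to 9.15. Per3, of the core clock, had means of 3.70 and 4.71 in places 1 to 3 and 5 to 8 of air and 1, 5 and 10 ppm. It had 5.16 to 6.82 at 40 and 120 ppm, and a slope of 0.19 ± 0.04 per place (limma adjusted p = 0.00203). The slopes of Ciart, Fkbp5 and Fmo2 did not pass (adjusted p = 0.932, 0.888 and 0.838), and their means were 3.37 and 3.43 for Ciart (4.91 to 7.23 at 40 and 120 ppm), 7.98 and 8.14 for Fkbp5 (9.34 to 10.29), and 4.53 and 4.36 for Fmo2 (5.83 to 7.48). The ranges of Fmo2 overlapped, since a mouse of places 1 to 3 in the lower groups had 5.935. Acot3 likewise reached 8.434 in a mouse of those places, within its range of 6.61 to 10.01 at 40 and 120 ppm.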
